A study of Mus musculus with 8 samples.

How the data were processed

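Single-colour expression arrays were made from total RNA of mouse olfactory mucosa, per the labels, with 2 arrays in each of 4 groups. Groups were taken from the sample titles. The deposited table holds one intensity value per probe set and array on a linear scale, as the authors processed them; the software and scaling are not given in the sources used here. The deposited intensity values had nearly equal means after trimming 2% at each end (within 0.00434% of their mean), so they were already scaled and were not normalized again. Dye direction does not apply, and the median per array was 581.4 to 660.3. Of 12488 probe sets, 10855 had 1 gene symbol in the platform annotation, 396 had several genes and were not named, and 1237 had none. Gene records of 16 named probe sets found no match in the GRCm38.p6 gene table, which was used only for names and neighbours.

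Values were analysed as log2(value + 102.3), with the 20th percentile of the table as the pseudocount, so differences of dim genes are understated. A probe set was tested where at least 2 arrays exceeded 362.7, the 40th percentile, which left 8150 probe sets and 6181 genes. limma (version 3.58.1, R 4.3.3) fitted all 4 groups together, which share one estimate of the spread with 4 residual degrees of freedom, with an intensity trend and Benjamini-Hochberg adjustment. The 7 comparisons were genotype after each injection, CCL3 in each genotype, their interaction, and the averages of both. The 30 lists of markers and pathways, fixed before the data were examined, were tested by camera with a preset correlation of 0.01 and again with an estimated one, with the brightest probe set for each gene and adjustment over the lists within a comparison. Fry tested the lists as well. Genes were named by a rule fixed before the data were examined: with no probe set past the threshold, those with the smallest p in each direction, Ccl3, Ccl4 and Ccr1, and up to 4 members of each list that passed, all given as not passing over all probe sets.

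The alternatives were other normalizations (quantile, one median, cyclic loess), other pseudocounts and a floor, other filters, no intensity trend, the replicate number as a block, only the groups compared, other thresholds, and each array left out in turn. A fit of 2 groups of 4 arrays for the averages, and the criteria near Ccl3, were added after seeing the data. A group left with 1 array is then assumed to vary like the others. The methods were tested on simulated data made from the real means and spreads of 8150 probe sets. For the genotype comparison after carrier, 24.8% of probe sets changed 2-fold and 94.0% of those changed 4-fold were recovered; for the genotype average 67.6% and 99.2%, and for the interaction 5.80% and 61.0%. The simulated noise was independent between genes, and each draw held 200 changed probe sets, from 2-fold to 16-fold. That many changes ease the adjusted threshold, so the shares may be lower where few probe sets change. They do not show that real changes of these sizes would have been found. Figures were drawn with matplotlib. An item of the naming rule is not reported here.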

Results

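RNA from mouse olfactory mucosa, the nasal tissue that holds the olfactory neurons, was measured on 8 single-colour expression arrays. All samples came from mice whose olfactory bulbs had been removed on both sides, an operation that takes away the target of the olfactory neurons. The arrays fall into 4 groups of 2: C57BL/6 wild-type mice and mice labelled Ccl3-/-, each injected with carrier or with CCL3, a chemokine that attracts macrophages and other leukocytes. The title of the series asks how CCL3 affects the macrophages that enter the olfactory epithelium after target removal. The table holds 12488 probe sets, of which 8150 passed the filter on dim signals, and the median intensity per array ranged from 581.4 to 660.3. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these arrays, which may be technical. With 2 arrays per group, the number of arrays limits the precision of every value.

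The Ccl3 probe set went against the genotype labels. Its intensity was 768.15 ± 46.0 (SD, n = 4) on the arrays labelled Ccl3-/- and 275 ± 103 (SD, n = 4) on the wild-type arrays. The single arrays ranged from 727 to 812 and from 159 to 386.5, without overlap. All wild-type arrays but CCL3 replicate 2 lay under the filter value of 362.7, so the wild-type signal was dim. On the log2 scale Ccl3 was 1.25 ± 0.25 (SE) higher on the arrays labelled Ccl3-/-, with an adjusted p of 0.590 in limma, so it did not pass the threshold over all probe sets. The labels do not say which part of the gene was deleted. If the probe set lies outside that part, it checks nothing. The groups are therefore named by their labels throughout, and every genotype direction rests on those labels. Ccl4, a neighbouring chemokine gene, and Ccr1, a receptor of CCL3, were below the filter, at 120 ± 48.5 and 291 ± 194 (SD, n = 4) on the arrays labelled Ccl3-/- and 82.3 ± 35.05 and 240 ± 42.5 (SD, n = 4) on the wild-type arrays.

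**Figure D1:**
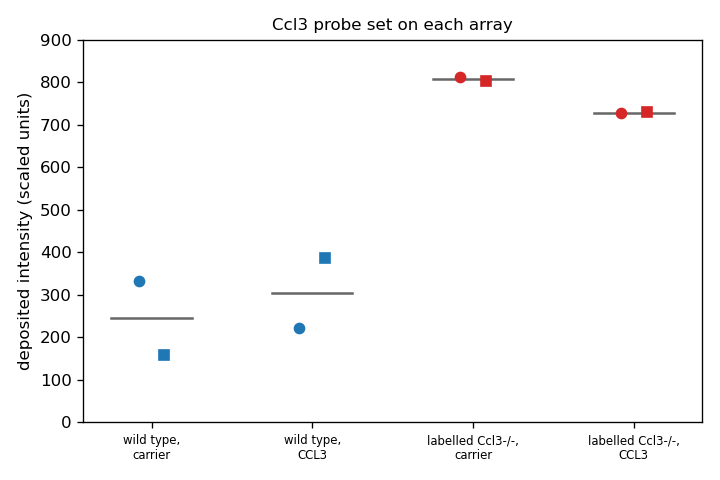
Intensity of the Ccl3 probe set as deposited (vertical axis, scaled units) on each of the 8 arrays by group (horizontal axis), with circles for replicate 1, squares for replicate 2 and lines for group means. The 4 arrays labelled Ccl3-/- sit between 727 and 812, all above the 4 wild-type arrays.

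Macrophage genes did not separate the groups in any comparison. Of 46 macrophage and microglia markers on the list, 38 were on the array and 25 passed the filter on dim signals. These 25 had mean log2 differences between -0.08 and 0.09 over the 7 comparisons, with adjusted p from 0.612 to 0.985 in limma's camera test. The other markers were not tested, so a change limited to them would be missed. After carrier, Cd68, a lysosomal protein of macrophages, was 0.44 ± 0.34 (SE, n = 2 per group) higher on the arrays labelled Ccl3-/-, and Adgre1, which encodes the macrophage antigen F4/80, was 0.32 ± 0.56 higher. Csf1r, the receptor for the growth factor CSF1, was at -0.35 ± 0.27. CCL3 against carrier on the arrays labelled Ccl3-/- gave 0.00 ± 0.34 for Cd68, 0.06 ± 0.56 for Adgre1 and 0.31 ± 0.27 for Csf1r. None of these differences exceeded the spread between replicates by limma. Cd68, Adgre1 and Csf1r were named outside the naming rule and do not stand for the whole list. After carrier, 1 of the 25 markers was higher and 2 were lower at an unadjusted p under 0.05 in limma. The 2 carrier arrays of the wild type lay at -0.15 and 0.08 around the list's mean over all arrays.

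After carrier injection, neutrophil genes were higher and neuronal precursor genes lower on the arrays labelled Ccl3-/- than on wild-type arrays. The 14 neutrophil markers had a mean log2 difference of 0.72 (adjusted p = 0.00458 in camera with a preset correlation, and adjusted p = 0.765 with an estimated correlation). Ngp, a neutrophil granule protein, was 5.34-fold higher (log2 2.42 ± 0.53 SE, n = 2 per group), and S100a8, a calcium-binding protein abundant in neutrophils, was 1.74 ± 0.68 higher on the log2 scale. The 15 markers of globose basal cells and neuronal precursors had a mean of -0.58 (adjusted p = 0.00205, and adjusted p = 0.765 with an estimated correlation), with 13 of them lower. Neurod1 and Neurog1, transcription factors of olfactory neuron precursors, were at -1.59 ± 0.35 and -0.95 ± 0.35, and Sox11 was at -1.29 ± 0.30. Adjusted over the list alone, 2 neutrophil genes and 2 precursor genes passed; over all probe sets, none did.

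Proliferation and lymphocyte lists also passed in this comparison. The 36 cell cycle genes had a mean of 0.35 (adjusted p = 0.0270, and adjusted p = 0.832 with an estimated correlation), led by Tk1 (1.34 ± 0.50) and the replication helicase gene Mcm7 (1.08 ± 0.42), while one probe set of the proliferation marker Mki67 was at -1.02 ± 0.40. The cell cycle mean was 0.02 without wild-type carrier replicate 1 and -0.14 without carrier replicate 2 labelled Ccl3-/-, and the call was lost in both fits, so it rested on those arrays. It was 0.69 without wild-type carrier replicate 2 and 0.84 without carrier replicate 1 labelled Ccl3-/-, and it lost the call with a filter at the 60th percentile (0.36) or all probe sets of a gene (0.30). All 10 T, B and NK cell markers were lower, with a mean of -0.49 (adjusted p = 0.0376, and adjusted p = 0.765 with an estimated correlation), among them the B cell genes Ms4a1 (-0.84 ± 0.28) and Cd79a (-0.81 ± 0.36). Without wild-type carrier replicate 2, the mean was 0.55 for neutrophil markers (adjusted p = 0.352), -0.47 for precursors (adjusted p = 0.134) and -0.33 for lymphocyte markers (adjusted p = 0.384). The lymphocyte call was also lost without carrier replicate 1 labelled Ccl3-/- (-0.34, adjusted p = 0.228) and with quantile normalization (-0.43), cyclic loess (-0.39) or all probe sets of a gene (-0.33). No probe set passed an adjusted p of 0.05 in limma (lowest 0.363), and 932 were under an unadjusted p of 0.05. Independent probe sets with no difference would give 408 in each comparison if all groups had the same spread. The counts for the interaction (412) and the genotype average (483) also lay above this, and the 4 others (121 to 399) below. One spread was fitted to all groups. Carrier arrays lay further from the mean of all arrays (root mean square 0.383 to 0.521) than CCL3 arrays (0.265 to 0.319). Unequal spread could raise the count after carrier and lower the one after CCL3, which was not tested. The smallest p for genotype after carrier belonged to Slfn2 (2.21 ± 0.39), B3galt2 (1.82 ± 0.35) and Pip (2.54 ± 0.49) among the higher. Among the lower it belonged to Alb (-2.04 ± 0.34), the MHC class II gene H2-Ab1 (-1.42 ± 0.24) and Clgn (-2.19 ± 0.39). Another probe set of Clgn went in the opposite direction. Wild-type carrier replicate 1 stood apart from the other arrays in its Gapdh 3' to 5' ratio, 2.59 against 0.755 to 1.31, and over its whole profile, as described below. Without wild-type carrier replicate 2, which leaves that array alone in its group, 110 probe sets passed.

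After CCL3 injection, red blood cell genes were higher on the arrays labelled Ccl3-/- than on wild-type arrays, and neutrophil markers were higher on average. All 8 red blood cell genes were higher, with a mean of 0.89 (adjusted p = 1.07e-12 in camera). This was the 1 list result of 32 that also passed with an estimated correlation (adjusted p = 0.0426). The estimate was -0.072 for red cell genes, -0.031 for leukocyte trafficking genes and 0.0215 for neutrophil markers, against the preset 0.01. For red cell and trafficking genes, which lie below the preset, a higher correlation between genes therefore does not account for the higher p. By limma's fry, which tests whether the genes of a list move on balance one way, the red cell list passed here (adjusted p = 0.0153), for CCL3 against carrier on the arrays labelled Ccl3-/- (adjusted p = 0.0114) and for the interaction (adjusted p = 0.0332). No other list passed by fry in any of the 7 comparisons, where the lowest adjusted p was 0.147 for neutrophil markers, 0.369 for precursors and 0.0967 for leukocyte trafficking genes. Alas2, the first enzyme of haem synthesis in red cells, was 2.27-fold higher (log2 1.18 ± 0.26 SE, n = 2 per group), the anion exchanger Slc4a1 was at 1.62 ± 0.43, and the beta globin gene Hbb-b2, whose copies can share signal, was at 0.70 ± 0.25. The neutrophil list had a mean of 0.72 (adjusted p = 0.00160, and adjusted p = 0.328 with an estimated correlation), led by Ngp (2.81 ± 0.53), Camp (2.36 ± 0.60) and Mpo (2.08 ± 0.59), all products of maturing granulocytes, while 8 of the 14 markers were higher and 6 lower. Without CCL3 replicate 1 labelled Ccl3-/- its mean was 0.43 (adjusted p = 0.0423). Adjusted over the list alone, 4 red cell genes and 3 neutrophil genes passed; over all probe sets, none did.

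The other lists that passed were lower in that comparison. The 27 immediate early and heat shock genes had a mean of -0.22 (adjusted p = 0.00346, and adjusted p = 0.535 with an estimated correlation), with Fos at -1.08 ± 0.33 and Egr1 at -0.69 ± 0.28. Horizontal basal cell markers had a mean of -0.24 (adjusted p = 0.0173) and gland secretory products one of -0.45 (adjusted p = 0.0236), each with an adjusted p = 0.535 with an estimated correlation. Wfdc18 was at -2.02 ± 0.42 and the mucin gene Muc5ac at -0.97 ± 0.40. Without CCL3 replicate 2 of the wild type the horizontal basal mean was -0.04 and the immediate early mean -0.16, and without CCL3 replicate 1 labelled Ccl3-/- they were -0.09 and -0.15. Both lists lost the call in each of these fits, immediate early genes with an adjusted p of 0.141 and 0.0742. The horizontal basal mean was -0.44 without CCL3 replicate 1 of the wild type and -0.39 without CCL3 replicate 2 labelled Ccl3-/-. The gland list lost the call without CCL3 replicate 2 labelled Ccl3-/- (-0.18, adjusted p = 0.355) and without CCL3 replicate 1 of the wild type (-0.43, adjusted p = 0.221). It was -0.73 without CCL3 replicate 1 labelled Ccl3-/-, and it lost the call with a filter at the 60th percentile (-0.41) or all probe sets of a gene (-0.38). In limma no probe set passed, with 121 under an unadjusted p of 0.05; the smallest p belonged to Med1, a subunit of the Mediator complex (1.74 ± 0.25, adjusted p = 0.332). With these 2 groups alone in the fit, Wfdc18 passed (adjusted p = 0.0197).

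On the arrays labelled Ccl3-/-, CCL3 against carrier went with higher red blood cell genes and lower leukocyte trafficking genes. All 8 red cell genes were higher, with a mean of 0.92 (adjusted p = 3.42e-07 in camera, and adjusted p = 0.123 with an estimated correlation), among them Hbb-b2 (1.20 ± 0.25 SE, n = 2 per group), Slc4a1 (1.65 ± 0.43) and the alpha globin gene Hba-a1 (0.91 ± 0.27). Of 18 leukocyte adhesion and trafficking genes 13 were lower, with a mean of -0.53 (adjusted p = 0.000497, and adjusted p = 0.163 with an estimated correlation). Selp, the P-selectin that slows leukocytes on vessel walls, was at -1.88 ± 0.60, the protease gene Mmp3 at -1.69 ± 0.54 and the protease inhibitor gene Timp1 at -1.05 ± 0.32. With a filter at the 60th percentile the trafficking list lost the call (-0.35, adjusted p = 0.0878). Adjusted over the list alone, 5 red cell genes and 0 trafficking genes passed; over all probe sets, none did.

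Another 6 lists passed in that comparison, none with an estimated correlation (adjusted p from 0.475 to 0.608). The complement and acute phase list had a mean of -0.50 (adjusted p = 0.0148) but a median of -0.02, since the acute phase genes Saa3 (-3.86 ± 0.97), Cp (-2.07 ± 0.51) and Orm1 (-1.67 ± 0.49) carried it. Horizontal basal cell markers (-0.41, adjusted p = 0.00341), immediate early and heat shock genes (-0.25, adjusted p = 0.0148) and oxidative stress genes (-0.27, adjusted p = 0.0264) were lower. Precursor markers (0.31, adjusted p = 0.0352) and lymphocyte markers (0.42, adjusted p = 0.0264) were higher. The 4 lower lists had an adjusted p from 0.212 to 0.547 without carrier replicate 2 labelled Ccl3-/-, with a complement mean of -0.36, a horizontal basal mean of -0.25, an immediate early mean of -0.07 and an oxidative stress mean of -0.16. Precursor and lymphocyte markers had means of 0.21 and 0.27, each at an adjusted p of 0.319, without carrier replicate 1 labelled Ccl3-/-. Without CCL3 replicate 1 labelled Ccl3-/- the lymphocyte mean was 0.22 (adjusted p = 0.250) and the oxidative stress mean -0.19 (adjusted p = 0.0640), and without CCL3 replicate 2 so labelled the precursor mean was 0.27 (adjusted p = 0.161). The immediate early mean was -0.43 without carrier replicate 1 labelled Ccl3-/-, and the horizontal basal mean -0.26 without CCL3 replicate 1 so labelled. Precursor markers lost the call with the pseudocount at the 40th percentile (0.23), no filter (0.25) or only the groups compared (0.31). Lymphocyte markers lost it with no filter (0.15) or all probe sets of a gene (0.32), and oxidative stress genes with quantile normalization (-0.23), no filter (-0.27) or all probe sets of a gene (-0.22). In limma no probe set passed (lowest adjusted p 0.722), with 399 under an unadjusted p of 0.05. The smallest p belonged to Lox (-1.88 ± 0.30, with another probe set near 0 at 0.10) and to the decoy interleukin 1 receptor gene Il1r2 (-1.71 ± 0.31 and -1.42 ± 0.30 by its 2 probe sets) among the lower and to Ltbp3 (1.55 ± 0.30) among the higher. Without carrier replicate 1 labelled Ccl3-/-, Wfdc18 passed at -2.47.

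In wild-type mice, CCL3 against carrier moved 1 list past the threshold. The 30 sustentacular cell and xenobiotic enzyme genes, from the supporting cells of the epithelium, had a mean of 0.26 with 22 of them higher (adjusted p = 0.0487 in camera, and adjusted p = 0.754 with an estimated correlation). The alcohol dehydrogenase gene Adh1 was at 0.80 ± 0.31 (SE, n = 2 per group) and the cytochrome P450 gene Cyp2f2 at 0.91 ± 0.39. The call was lost under 9 of 13 other settings and without wild-type carrier replicate 1 (mean 0.19), wild-type carrier replicate 2 (0.33) or wild-type CCL3 replicate 2 (0.18). In limma no probe set passed (lowest adjusted p 0.376), with 350 under an unadjusted p of 0.05. The smallest p belonged to Arhgef2 (-1.66 ± 0.28) and Alb (-1.79 ± 0.34) among the lower named genes and to Itih2 (1.51 ± 0.28) among the higher. Without wild-type carrier replicate 2, 73 probe sets passed.

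The CCL3 difference itself was set against the other genotype for every list. The interaction was positive for red blood cell genes (mean 1.06, adjusted p = 0.000248), whose CCL3 difference was 0.92 on the arrays labelled Ccl3-/- and -0.14 in the wild type. It was positive too for precursor markers (0.55, adjusted p = 0.00703), with 0.31 and -0.24. The interaction was negative for horizontal basal cell markers (-0.59, adjusted p = 0.00703), whose CCL3 difference was -0.41 on the arrays labelled Ccl3-/- and 0.19 in the wild type. It was also negative for gland secretory products (-0.93, adjusted p = 0.0129), with -0.13 and 0.80. With an estimated correlation the adjusted p was 0.298 for red cell genes and 0.662 for the others. Rhd, which encodes a red cell surface protein, had an interaction of 2.58 ± 0.72 (SE, n = 2 per group), Neurod1 one of 1.64 ± 0.50, the keratin gene Krt17 one of -1.56 ± 0.62 and Muc5ac one of -1.71 ± 0.57. Precursor and horizontal basal markers both lost the call without wild-type carrier replicate 2 (0.45 and -0.59) and without wild-type CCL3 replicate 2 (0.41 and -0.40), and horizontal basal markers also without carrier replicate 2 labelled Ccl3-/- (-0.42). Gland products lost it without carrier replicate 2 (-0.82) or CCL3 replicate 2 (-0.65) labelled Ccl3-/-, and with quantile normalization (-0.87), cyclic loess (-0.92) or a filter at the 60th percentile (-0.89). Their interaction was -0.42 without wild-type carrier replicate 1 (adjusted p = 0.0361) and -1.43 without wild-type carrier replicate 2. In limma no probe set passed for the interaction (lowest adjusted p 0.908), with 412 under an unadjusted p of 0.05.

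**Figure D2:**
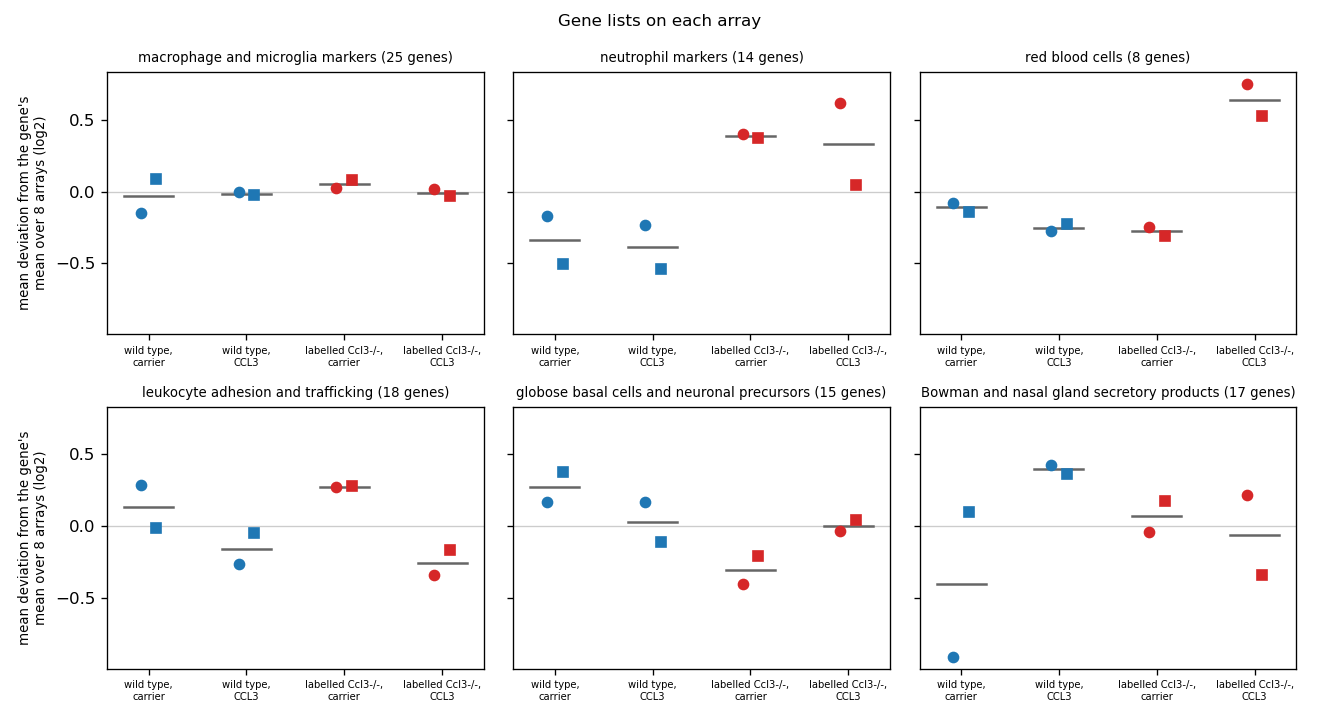
Mean deviation of 6 gene lists from each gene's mean over the 8 arrays (vertical axis, log2) on each array by group (horizontal axis), with circles for replicate 1, squares for replicate 2 and lines for group means. Red blood cell genes lie at 0.75 and 0.52 on the CCL3 arrays labelled Ccl3-/- and below 0 on the others, while macrophage markers stay between -0.15 and 0.08.

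Averaged over both injections, neutrophil markers were higher on the 4 arrays labelled Ccl3-/- than on the 4 wild-type arrays. Their mean difference was 0.72 with 12 of 14 genes higher (adjusted p = 3.38e-05 in camera, and adjusted p = 0.306 with an estimated correlation). Ngp was at 2.61 ± 0.38 (SE, n = 4 per group), Camp at 1.81 ± 0.43 and S100a8 at 1.60 ± 0.48. Smaller neutrophil sets, drawn up after the results were seen, differed by injection. Mature circulating neutrophil genes were at 0.97 after carrier, with 5 of 6 higher, and at 0.19 after CCL3, with 2 of 6. Granule genes of neutrophil precursors were at 0.76 after carrier, with 3 of 5 higher, and at 1.84 after CCL3, with 5 of 5. The average need not stand for a single increase shared by both injections. Red cell genes (0.36, adjusted p = 0.00650) and cell cycle genes (0.24, adjusted p = 0.00784) were higher, though red cell genes were at -0.17 after carrier, with 2 of 8 higher, and at 0.89 after CCL3. By average, precursor (-0.30, adjusted p = 0.00255) and lymphocyte markers (-0.30, adjusted p = 0.0171) were lower. With an estimated correlation these 4 had an adjusted p from 0.364 to 0.771. The cell cycle mean was 0.07 without wild-type carrier replicate 1, 0.19 without wild-type CCL3 replicate 2, -0.01 without carrier replicate 2 labelled Ccl3-/- and 0.17 without CCL3 replicate 1 so labelled, and the call was lost in all 4 fits (adjusted p from 0.0793 to 0.870). It was 0.40 without wild-type carrier replicate 2 and 0.48 without carrier replicate 1 labelled Ccl3-/-, and it lost the call with a filter at the 60th percentile (0.22). Without wild-type carrier replicate 2, red cell, precursor and lymphocyte means were 0.34, -0.25 and -0.23, with adjusted p from 0.116 to 0.271. The precursor call was also lost without wild-type CCL3 replicate 1 (-0.23), and the lymphocyte call without carrier replicate 1 (-0.23) or CCL3 replicate 2 (-0.20) labelled Ccl3-/- and with all probe sets of a gene (-0.26). In limma no probe set passed; Med1 was closest (1.47 ± 0.18, adjusted p = 0.0715), and 483 were under an unadjusted p of 0.05. Without carrier replicate 2 labelled Ccl3-/-, Wfdc18 passed at -1.61. With 2 groups of 4 arrays in the fit, a choice made after seeing the data, Med1 and Ngp passed (each with an adjusted p = 0.0295), 434 probe sets were under an unadjusted p of 0.05, and the red cell list lost the call (adjusted p = 0.0555).

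Averaged over both genotypes, leukocyte adhesion and trafficking genes were lower on the CCL3 arrays. Their mean was -0.41 with 15 of 18 genes lower (adjusted p = 0.000126 in camera, and adjusted p = 0.228 with an estimated correlation), among them Mmp3 (-1.56 ± 0.38 SE, n = 4 per group) and Selp (-1.57 ± 0.43). Red cell genes (0.39, adjusted p = 0.00176), MHC class II genes (0.32, adjusted p = 0.0152) and sustentacular genes (0.16, adjusted p = 0.0325) were higher, though red cell genes were at -0.14 in the wild type, with 3 of 8 higher, and at 0.92 on the arrays labelled Ccl3-/-. The complement and acute phase list had a mean of -0.33 (adjusted p = 0.0152) and a median of -0.03, with Saa3 at -2.94 ± 0.68. With an estimated correlation these 4 had an adjusted p from 0.245 to 0.839. Single arrays ended several of these calls. Without wild-type carrier replicate 1, MHC class II had a mean of 0.13 and sustentacular genes one of 0.12; without wild-type carrier replicate 2, red cell genes had 0.37, complement -0.34 and sustentacular genes 0.19, while MHC class II kept the call at 0.50. Without wild-type CCL3 replicate 1, MHC class II had 0.31 and complement -0.26; without carrier replicate 2 labelled Ccl3-/-, complement had -0.26 and sustentacular genes 0.12. Sustentacular genes also lost the call without wild-type CCL3 replicate 2 (0.12) or CCL3 replicate 2 labelled Ccl3-/- (0.06), and had 0.26 without CCL3 replicate 1 so labelled. Sustentacular genes lost it with cyclic loess (0.14), no filter (0.12) or a filter at the 60th percentile (0.14), complement with no filter (-0.33) and MHC class II with a filter at the 60th percentile (0.29). In limma no probe set passed (lowest adjusted p 0.109), with 369 under an unadjusted p of 0.05, and Lox was lowest among named genes (-1.42 ± 0.22). Without wild-type carrier replicate 2, 23 probe sets passed.

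Whether CCL3 moved genes of the arrays labelled Ccl3-/- back towards wild type was tested over all probe sets. The covariance of the genotype difference after carrier with the CCL3 difference on the arrays labelled Ccl3-/- was -0.114. These differences share the same carrier arrays, so the value was set beside 384 draws with no effect. The draws gave a mean of -0.0761, with a range from -0.155 to -0.0196, so the value lay inside what shared arrays give. They only rearranged the replicate differences within the groups and flipped their signs. Many draws therefore repeat the same value, and the range is coarse. Genotype differences after carrier and after CCL3 had a correlation of 0.0538 across probe sets, which are not independent replicates, against a range of -0.227 to 0.227 in those draws.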

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

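The tests of explanations in this part were chosen after the results were seen; the interaction test was planned. The interaction test marked 4 lists whose CCL3 difference differed between genotypes: red blood cells (1.06), globose basal cells and neuronal precursors (0.55), horizontal basal cells (-0.59) and gland secretory products (-0.93). None of the 4 passed with an estimated correlation, and by fry red blood cells passed (adjusted p = 0.0332) and the other 3 did not.

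Red blood cell genes were higher on both CCL3 arrays labelled Ccl3-/- than on any other array, and the sets below compare CCL3 with carrier on the arrays so labelled unless stated. More blood in the tissue might raise all 8 genes by a common factor, though the pseudocount shrinks the differences of dim genes. Their dispersion over their standard errors was 1.96, just under the limit of 2.01 set beforehand for this test. That limit treats the genes as independent, while all share the same arrays, so the value does not decide the question. Blood would also bring genes of mature circulating neutrophils, yet these were lower (mean log2 difference -0.65, camera p = 0.00234, p = 0.0356 with an estimated correlation; 0.19 for genotype after CCL3, camera p = 0.804), which the tissue's own neutrophils may obscure. Bone marrow in the sample could bring granule genes of neutrophil precursors, and these 5 genes were higher (mean 0.83, camera p = 0.00309, p = 0.131 with an estimated correlation), also for genotype after CCL3 (1.84, camera p = 5.97e-15, p = 0.00741 with an estimated correlation), but they were at 0.76 for genotype after carrier (camera p = 0.0501), where red cell genes were at -0.17, and the set was drawn up after several members had been seen to be high. Blood, marrow and an effect of CCL3 itself cannot be told apart with 2 arrays per group.

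The Ccl3 signal was 2.79 times as high on the arrays labelled Ccl3-/- as on wild-type arrays, where it was mostly under the filter value. As already seen before this test was chosen, 0 arrays lay in the range of the other genotype. This argues against a single wrong label only if the signal follows the genotype, which is not known. An exchange of all genotype labels, or a probe set outside the deleted part, cannot be told apart from the labelled design. DNA of another strain around Ccl3 might give more genotype differences there: at an unadjusted p under 0.01, 4 of 91 genes within 10 Mb differed (Wfdc18, Slfn2, Akap1 and Ccl9) against 46 of 6079 elsewhere, an odds ratio of 6.03 (Fisher's exact p = 0.00608, adjusted p = 0.0299 over 56 such tests of windows, thresholds and comparisons). This criterion was picked because no gene passed the planned one, and p was 0.05 or more in 4 of 8 fits that left out an array (odds ratio 0 without wild-type CCL3 replicate 1). The carrier arrays alone gave 1.98 (Fisher's exact p = 0.157) and the CCL3 arrays alone 11.5 (Fisher's exact p = 0.00341, adjusted p = 0.0273). A 5 Mb window gave 10.2 (Fisher's exact p = 0.00430). Of the 4 genes, only Akap1 separated the genotypes on every array (833 to 1632 in wild type, 1952 to 2494 on the arrays labelled Ccl3-/-). Wfdc18, Slfn2 and Ccl9 overlapped between genotypes. Over whole chromosomes, 1.85% of genes differed on chromosome 11 and 2.86% on chromosome X. CCL3 against carrier in wild type, where the strain is the same, gave an odds ratio of 5.14 (Fisher's exact p = 0.0251, adjusted p = 0.0935). The excess therefore stays an open hypothesis.

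Wild-type carrier replicate 1 stood apart, with a Gapdh 3' to 5' ratio of 2.59 (0.755 to 1.31 on the 7 others). It also stood apart over the whole profile. On the main axis of variation between arrays (28.7% of the variance) it lay at -46.5, against -1.14 to 13.6 on the 7 others. Its root mean square deviation from the mean of all arrays was 0.521, against 0.265 to 0.418. Every comparison that uses the wild-type carrier group rests in part on this array. RNA degraded from the 5' end would raise the beta-actin ratio too, which was 1.58 and below the 7 others (1.61 to 2.17). Less gland tissue may be part of the difference. The gland list lay at -0.91 on this array and at -0.34 to 0.43 on the 7 others. Gapdh, which is not on that list, was low too. Its 5' and middle signals were 9448 and 12109, against at least 26787 and 34446 on the 7 others. A lower gland share was not shown to account for this or for the whole profile. Whether tissue content moves the Gapdh ratio was not tested, and the cause of that ratio stays open.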

How the results depend on the processing

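The alternatives were planned, except those of the odds ratio near Ccl3 and the fit of 2 groups, which were chosen after seeing the data; the cause of each move was not tested. Replicate numbers did not pair the arrays (correlations from -0.158 to 0.178); with the replicate block 1 probe set passed for genotype after carrier (Pip), for the genotype average (Ngp) and for the CCL3 average. With only the groups compared, 1 passed for genotype after CCL3. A fit of 2 groups gave 2 for the genotype average (Med1 and Ngp). At an adjusted p under 0.1, 1 passed for the genotype average. An unadjusted p under 0.05 with 1.5-fold gave 897 for genotype after carrier, 118 after CCL3, 385 for CCL3 in the labelled knockout, 341 in wild type, 412 for the interaction, and 273 and 216 for the genotype and CCL3 averages. Leaving out each array gave 0 to 110 for genotype after carrier, 0 to 1 after CCL3, 0 to 1 for CCL3 in the labelled knockout, 0 to 73 in wild type, and 0 to 1 and 0 to 23 for the averages. With an estimated correlation, lists passing fell to 0, with 1 for genotype after CCL3. For CCL3 in wild type 0 lists passed with quantile, median or loess scaling, a 5th percentile pseudocount, a floor, a 60th percentile filter, no trend or all probe sets, and 2 with no filter. No filter gave 5 for CCL3 in the labelled knockout and 3 for the CCL3 average; the 60th percentile filter gave 2 for genotype after carrier and 3 for the CCL3 average; all probe sets gave 2 for genotype after carrier. Leaving out each array gave 1 to 9 lists (genotype after carrier), 5 to 8 (after CCL3), 6 to 13 (CCL3 in the labelled knockout), 0 to 4 (wild type), 2 to 12 (interaction), 2 to 7 and 2 to 12 (averages). Of 32 passing list results, 7 kept the call without each array. Uncalled macrophage means changed sign: for genotype after CCL3 -0.005895 (quantile), -0.028 (median), -0.009584 (loess), -0.0177 (no filter) and -0.002054 (60th percentile); for the CCL3 average 0.006404, 0.0252 and 0.0965 (quantile, median, 60th percentile); for CCL3 in wild type -3.44e-05 (floor), -0.0624 (no filter) and -0.00947 (all probe sets); 0.0268 in the labelled knockout (60th percentile) and 0.0009373 for the interaction (all probe sets). Leaving out arrays, macrophage means ranged from -0.0312 to 0.20 (genotype after carrier), -0.0174 to 0.0295 (after CCL3), -0.10 to 0.13 (CCL3 in wild type), -0.20 to 0.0373 (interaction), -0.0126 to 0.10 (genotype average) and -0.0802 to 0.0364 (CCL3 average); Ccl3 from -0.12 to 0.61 (CCL3 in wild type) and -0.13 to 0.24 (CCL3 average); and cell cycle from -0.14 to 0.84 (genotype after carrier) and -0.00752 to 0.48 (average). The odds ratio near Ccl3 was 0 to 7.64 without each array, 1.43 and 1.38 at p under 0.05 within 20 Mb and over the chromosome, and 1.98 on carrier arrays. Named genes kept their direction and side in 3553 of 3572 settings, passed in 15 and changed sign in 4, all for Ccl3. No named gene passed in the main fit, so keeping the side meant staying uncalled. The count therefore says little about how firm the named differences are.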

Other observations

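The list tests in this part were planned, and the statistics counted over splits of the arrays were chosen after the results were seen. Other tissue components showed no list past the threshold: 17 of the 30 lists passed in no comparison (lowest adjusted p 0.0650). Mature olfactory neuron markers had mean log2 differences from -0.07 to 0.15 over the 7 comparisons, immature neuron markers from -0.19 to 0.19, and odorant and vomeronasal receptors from -0.18 to 0.16. Interferon response genes ranged from -0.08 to 0.07, MHC class I genes from -0.17 to 0.04, phagocytosis and lysosome genes from -0.16 to 0.19, cytokines from -0.12 to 0.21, chemokines from -0.43 to 0.08 and chemokine receptors from -0.36 to 0.47. Endothelial markers ranged from -0.13 to 0.00, fibroblast genes from -0.19 to 0.24, ensheathing glia from -0.14 to 0.08, apoptosis genes from -0.17 to 0.06, ciliated cells from -0.34 to 0.46, bone and cartilage from -0.03 to 0.23 and skeletal muscle from -0.32 to 0.42.

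Other groupings of the arrays gave results as large as the real ones. The splits were fitted with 2 groups, so the real counts differ from those of the fit of 4 groups (483 and 369 probe sets, 5 and 5 lists). Of the 35 splits of the 8 arrays into 4 and 4, 11 gave as many probe sets at an unadjusted p under 0.05 as the genotype split (434, highest other 837), and 15 as many as the injection split (340, highest other 837). As many lists passed in 18 splits as for genotype (4, highest other 9) and in 12 as for injection (5, highest other 9). Each of these counts of splits includes the real split itself. Chance therefore cannot be excluded for these counts, which ranged from 158 to 837 probe sets over the 35 splits.

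At an adjusted p under 0.05, the genotype split gave 2 probe sets in that fit (Med1 and Ngp) against 0 in the fit of 4 groups. It was the 1 split of 35 with as many (highest other 1), and 33 splits gave 0. A share of 1 in 35 is the lowest these splits allow, the fit and this count were chosen after the data were seen among 9 statistics counted over the splits, and the lead is 1 probe set, so chance is not excluded.

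The neutrophil list for genotype (0.72, highest other 0.61) and the leukocyte adhesion list for injection (0.41 in size, highest other 0.39) were each largest in the real split, 1 of 35. Both lists were picked because they held without each array in turn, out of 30 lists. When any list may count, some list reached a camera p as low as theirs in 15 and 13 of the 35 splits. Both counts include the real split. The -log10 p was 5.76 and 5.82 in the real splits, and the highest other was 18.8. So chance is not excluded for the choice of these lists, and both remain hypotheses.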
